A study of Arabidopsis thaliana and Hordeum vulgare and Setaria italica with 13 samples.

How the data were processed

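Seedlings were grown in soil at 23 ºC with 16 h of light and 8 h of darkness and collected at 10 days, per the labels' protocols, and total RNA was extracted with TRIzol and pretreated with a kit for tRNA fragments. For tRNA-seq the pretreated RNA entered a small RNA library kit. For YAMAT-seq a Y-shaped adapter was ligated with T4 RNA ligase 2 and the cDNA was amplified with 12 PCR cycles, per the labels' protocols. Ligation, reverse transcription past modified bases and PCR can each favour some tRNAs, so a share is one of sequenced cDNA. The submitters' processing notes name cutadapt and the A. thaliana build TAIR10, also for the other species. The aligner, the set of reference tRNAs per species, the treatment of reads that match several tRNAs and any length filter are not given in the sources used here.

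The tRNA-seq values were deposited as a percent of the total tRNA abundance of each library per anticodon, per the file headers, for 52 anticodons. The columns summed to between 98.05 (S. bicolor) and 100.47 (A. thaliana). Whether reads of tRNA fragments enter the percentages is not given in the sources used here. The depth is unknown, so these values have no interval. The YAMAT-seq values were deposited as raw counts of reads per tRNA sequence with its CCA end, per the file headers, with a lowest count of 1, so sequences without reads are not listed. In these counts 95% Clopper-Pearson intervals were computed for every share.

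Each library was its own group, taken from the sample titles. The A. thaliana leaf and root columns of tRNA-seq were averaged by the design and turned out identical, so that A. thaliana counted once. The anticodon of each YAMAT-seq sequence was taken from its name in A. thaliana and read from the sequence by a rule on the anticodon loop in the grasses. This rule gave the listed anticodon in 142 of 143 A. thaliana sequences and in 637 of 647 TAIR10.1 tRNA genes. IleCAT tRNAs cannot be told from MetCAT by the gene sequence of the anticodon, and their reads were counted with it. The 1 nuclear gene annotated as IleCAT stayed a family of its own in the gene counts. In TAIR10.1, 136 of the A. thaliana sequences had an exact match after removal of the 3 bases CCA; only these have coordinates.

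An A. thaliana sequence with an exact match took the type (plastid, mitochondrial or nuclear) of that place, and an organelle match came before a nuclear one. Every other sequence took the type of the nearest A. thaliana tRNA by edit distance (edlib 1.3.9.post1), with at most 16 edits and a gap of at least 5 edits to the next type, or was called plastid or mitochondrial where only nuclear tRNAs were set apart by that gap. The design allowed a compartment only if the files named it, which they did not, so this result and its limits were added after the data were examined; at most 12 edits with a gap of 3 and at most 20 edits with a gap of 8 were also tried. Nuclear tRNA genes per anticodon were counted in the TAIR10.1 annotation (608 genes in 47 families), and 17 nuclear genes within 1 edit of an organelle tRNA were left out, since they cannot be told from copies of it. Amino acid use was counted over 27444 proteins.

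Ratios between assays and between species groups were log2 ratios of percent + 0.01. This pseudocount was not fixed before the data were examined, and 0.001, 0.1 and 1 were tried. For a family near 0 in 1 assay the size of the log2 ratio is set by it, so such families are described by their shares. Assays were compared with a two-sided exact sign-flip permutation test over the 5 species for each of the 52 families, with Benjamini-Hochberg adjustment. Relations in A. thaliana were tested with 100000 resamples. The planned interval on the ratio between assays was not computed because 1 side has no counts. A first version of the calculations tested families with a mean of at least 0.1% in the comparison of assays, used values of 0 in the rank correlations and judged the relations in A. thaliana by unadjusted p; the design fixed before the data were examined was then restored, and the first 2 of these choices are given among the alternatives.

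Families were named if they were among the 5 largest of any library, among the 10 largest rises or falls between assays with a mean of at least 0.1%, or among the up to 10 with the largest log2 ratio between grasses and eudicots that did not overlap; this rule names 30 families. Lists fixed before the data were examined were Gly and Ala, Leu and Ser, Glu, Met, Asp and Glu, Arg, Lys and His, the aromatic residues, the first anticodon base, the G and C content of the anticodon and entries that are not standard tRNAs. Leu and Ser was fixed as a list of nuclear tRNAs, but its families were taken over all compartments, since the tRNA-seq values name none. ThrGGT, named beside a count of 6, and GlyTCC, IleAAT, LeuTAA, AlaCGC, TyrGTA and IleGAT fall outside the rule and were named after their values were seen, as were smaller families of a set of anticodons.

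The calculations used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. They were tested on simulated data. For the comparison of assays, 10 of 52 families were changed by a log2 of 4 in 200 runs with a log2 spread of 1 between species: 99.95% of the changed families had 1 direction in 5 of 5 species, 0 had the wrong one, and 6.45% of unchanged families also did. In the data the spread differed by family, with an SD of 0.88 for GlyGCC and 4.91 for GlnTTG. Simulated shares were also not rescaled to a fixed total, so these rates need not hold for the data. For YAMAT-seq shares 95.2% of 900 intervals held the true share. For abundance against gene number, 6% of 300 unrelated pairs had a permutation p under 0.05, and 100 of 100 related pairs were found. The related pairs had noise of the same spread as the signal, a stronger relation than those observed. The simulation therefore does not tell whether a relation of the observed size would be found.

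Alternatives fixed before the data were examined were shares without the most abundant family, leaf or root alone, amino acid sums, Pearson's r, a minimum of 100 counts or 0.1%, a minimum of 10 counts, a median-ratio size factor and the comparison without A. thaliana. Left out were all intervals on tRNA-seq values, any comparison of leaf with root, and genome coordinates of grass and soybean tRNAs, whose genomes were not used here.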

Results

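The abundance of tRNAs was profiled in seedlings of 7 plant species by 2 sequencing assays, in 13 libraries with 1 library per group. The tRNA-seq libraries, made with a small RNA kit from RNA pretreated for the sequencing of tRNAs and their fragments, covered leaf and root of Arabidopsis thaliana and seedlings of soybean (Glycine max), barley (Hordeum vulgare), sorghum (Sorghum bicolor), foxtail millet (Setaria italica), wheat (Triticum aestivum) and maize (Zea mays). The YAMAT-seq libraries, in which a Y-shaped adapter is joined to both ends of a tRNA through its CCA tail and thereby selects full-length mature tRNAs, covered A. thaliana, H. vulgare, S. italica, T. aestivum and Z. mays. tRNA-seq values were percentages of the tRNA abundance of a library over 52 anticodons, and the depth behind them is unknown. YAMAT-seq values were read counts per tRNA sequence, with totals of 13439654 in A. thaliana, 13059898 in H. vulgare, 6851530 in S. italica, 10517776 in T. aestivum and 19833183 in Z. mays. A family below is the set of tRNAs with 1 anticodon, written as the amino acid and the anticodon in DNA letters (GlyGCC). No group had a replicate, so no difference between 2 libraries could be set against a replicate spread. Intervals on YAMAT-seq shares are exact Clopper-Pearson 95% intervals and cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

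The question of how leaf and root of A. thaliana differ could not be answered from the values. GlnCTG, the largest family, stood at 21.4% in both columns, and ProTGG stood at 9.67% in both. All 52 anticodons were identical to the last digit in the leaf and root columns, and 0 differed. None of the other 27 pairs of tRNA-seq columns was identical, and the largest share of equal nonzero values in any of them was 0%. Values of 2 libraries sequenced and counted apart would differ by sampling noise at least, so the columns do not hold 2 measurements. Whether 1 column was copied or the libraries were pooled is not given in the sources used here, and the tissue behind the values is thus open. They were counted as 1 sample of A. thaliana, and leaf and root were not compared.

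The tRNA pools of the 7 species were led by different families in tRNA-seq. GlnCTG led in A. thaliana at 21.4%, ahead of ProTGG at 9.67%, GluTTC at 8.64%, MetCAT at 7.71% and LeuTAG at 6.0%. AspGTC led in G. max at 25.7%, ahead of SerAGA at 16.0% and GluCTC at 13.3%. SerGGA and SerGCT together led in Z. mays at 25.8% and 25.1% and in S. italica at 21.4% and 16.9%, and SerGCT was 2.71% in S. bicolor. In S. bicolor HisGTG at 17.8%, ThrTGT at 16.8%, AsnGTT at 13%, GluCTC at 6.89% and SerCGA at 5.58% stood highest. ValAAC at 11.4%, ThrTGT at 9.50% and LeuAAG at 9.38% led in H. vulgare, and GluCTC at 14.1%, MetCAT at 12.5%, GlnTTG at 9.30% and GlyGCC at 9.25% led in T. aestivum.

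The number of families that made up 50% of a library was 2 in Z. mays, 3 in G. max, 4 in S. bicolor and S. italica, 5 in A. thaliana and T. aestivum and 6 in H. vulgare. Of the 52 anticodons, 35 were above 0 in all 7 species. Spearman's rho across the families found in both libraries had a median of 0.551 over the 21 pairs of species and ranged from 0.349 between A. thaliana and S. bicolor to 0.913 between H. vulgare and T. aestivum. The median was 0.568 among grasses and 0.519 between grasses and eudicots. Families are not independent replicates, so these rank correlations describe the libraries and carry no p-value. With families of a mean of at least 0.1% alone, the median of the 21 pairs was 0.363.

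**Figure D1:**
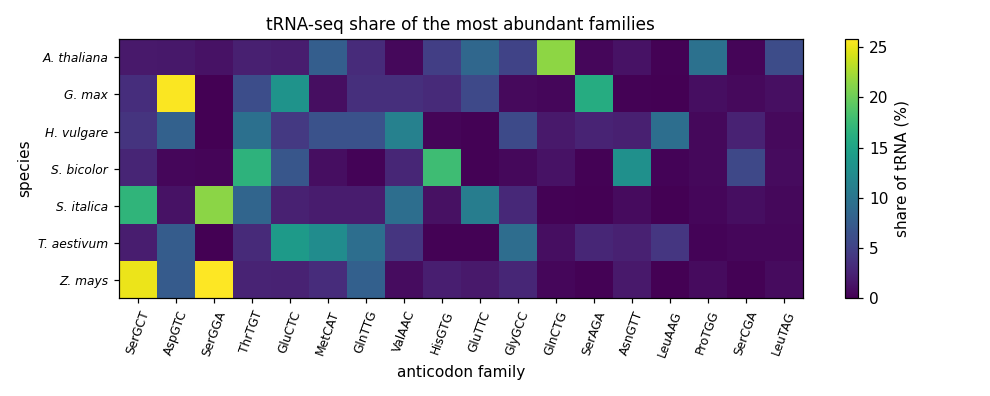
Share of the leading anticodon families in the tRNA-seq library of each species, in percent of the tRNA abundance of that library (colour scale; 1 cell per species and family, 1 library per species). SerGGA stood at 25.8% in Z. mays and 21.4% in S. italica and was listed at 0 in H. vulgare and T. aestivum.

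In the comparison of the 5 grasses with the 2 eudicots, ThrCGT, ValCAC and ArgACG were higher in every grass than in either eudicot. ThrCGT was 2.18% ± 1.62 (SD, n = 5 species) in grasses and averaged 0.103% in eudicots, a log2 ratio of 4.28 on the scale of percent + 0.01. ArgACG was 0.745% ± 0.715 (SD, n = 5) against 0.187%, and ValCAC was 0.249% ± 0.177 (SD, n = 5) against 0.0297% in A. thaliana and a value listed at 0 in G. max. ProTGG, LeuTAG, LeuCAA, LysTTT and ValGAC were lower in every grass than in either eudicot. ProTGG was 0.511% ± 0.169 (SD, n = 5) against 9.67% in A. thaliana and 0.927% in G. max, LeuTAG was 0.653% ± 0.123 (SD, n = 5) against 6.0% and 1.02%, and LeuCAA was 1.41% ± 1.00 (SD, n = 5) against 3.03% and 3.69%. LysTTT and ValGAC were minor families. LysTTT was 0.277% in A. thaliana and 0.0390% in G. max against at most 0.0289% in a grass, and ValGAC was 0.188% and 0.195% against 0.134% in Z. mays and values listed at 0 in the other 4 grasses. Whether the reference tRNAs of those 4 grasses held ValGAC is not given in the sources used here, so a 0 need not mean a lower abundance.

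These 8 of 52 families had groups that did not overlap, where chance gives 9.52% of families, or 4.95. Of the 21 ways to set 2 of the 7 species apart from the other 5, this one gave 8 families and 1 other gave more, with 10 for H. vulgare and T. aestivum, while the rest gave 1 to 7. With this one counted, 2 of 21 splits gave at least as many, a share above 0.05, and with amino acid sums in place of anticodons 0 groups did not overlap.

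In YAMAT-seq, GlyGCC was the largest family in every species. Its share was 55.3% (95% interval 55.28 to 55.34) in A. thaliana, 76.1% (76.05 to 76.09) in H. vulgare, 89.5% (89.50 to 89.55) in S. italica, 84.4% (84.37 to 84.41) in T. aestivum and 95.1% (95.12 to 95.14) in Z. mays. GlnTTG followed at 22%, 14.1%, 6.57% and 9.81% in A. thaliana, H. vulgare, S. italica and T. aestivum, but held 487 reads, or 0.00246% (0.00224 to 0.00268), in Z. mays. AspGTC lay between 2.97% in S. italica and 7.21% in H. vulgare. SerGCT held 9.94% (9.93 to 9.96) of the reads in A. thaliana and 2, 77, 4 and 0 reads in H. vulgare, S. italica, T. aestivum and Z. mays. Whether the reference tRNAs of the grasses held a plastid SerGCT, and those of Z. mays a plastid GlnTTG, is not given in the sources used here.

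Among the smaller families, MetCAT held 1.82% in H. vulgare, 1.16% in T. aestivum, 0.254% in S. italica, 0.242% in Z. mays and 0.0321% in A. thaliana. TrpCCA held 1.83% in A. thaliana and between 0.0324% and 0.220% in the 4 grasses. ArgTCT ranged from 0.155% in T. aestivum to 0.410% in Z. mays, CysGCA from 0.0256% in Z. mays to 0.676% in A. thaliana, and GluCTC from 0.0549% in T. aestivum to 0.462% in A. thaliana. Spearman's rho across the families found in both libraries had a median of 0.852 over the 10 pairs of species. It lay between 0.830 and 0.969 among the grasses, highest between H. vulgare and T. aestivum, and between 0.538 and 0.754 for A. thaliana with a grass.

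The reads came from very few sequences. In every species 1 tRNA sequence, of GlyGCC, made up over 50% of the reads. The number of sequences that made up 90% of the reads was 4 in A. thaliana, 2 in H. vulgare, S. italica and T. aestivum and 1 in Z. mays, out of 143, 86, 80, 151 and 72 sequences. The most abundant sequence of a family held a median of 96.9% of the reads of its family in A. thaliana, 99.9% in H. vulgare, 97.1% in S. italica, 98.7% in T. aestivum and 99.9% in Z. mays, and between 11 and 14 families per library held 1 sequence alone. Fewer than 10 reads stood behind 41, 44, 26, 88 and 28 of the sequences.

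The leading A. thaliana sequences were identical to tRNA genes of the organelle genomes in TAIR10.1. The GlyGCC sequence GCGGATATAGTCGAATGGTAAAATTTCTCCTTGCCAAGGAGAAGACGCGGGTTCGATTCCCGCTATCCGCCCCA, with 7431104 reads or 55.3%, matched the plastid genome at positions 36490 to 36560 on the plus strand, in the tRNA gene ArthCt116. GlnTTG with 2919301 reads matched ArthCt090 (plastid, 6616 to 6687, minus strand). SerGCT with 1290264 reads matched the sequence at 7785 to 7872 of the plastid genome on the minus strand, where ArthCt091 is annotated on the other strand, AspGTC with 491783 reads matched ArthCt095 (plastid, 29801 to 29874, minus strand), and TrpCCA with 245275 reads matched ArthCt105 (plastid, 66229 to 66302, minus strand). The leading mitochondrial sequence was CysGCA with 87470 reads (DA397_mgt04, mitochondrial genome, 42546 to 42616), and the leading nuclear sequence was AspGTC with 62129 reads, or 0.462%, which matched 21 places, among them AT1G03515 (chromosome 1, 877648 to 877719, plus strand).

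Sequences nearest to a nuclear A. thaliana tRNA held 1.35% (1.348 to 1.360) of the reads in A. thaliana, 0.580% (0.576 to 0.585) in H. vulgare, 0.759% (0.752 to 0.765) in S. italica, 0.289% (0.286 to 0.293) in T. aestivum and 0.282% (0.280 to 0.284) in Z. mays. Plastid sequences held 96.8% and mitochondrial sequences 1.81% in A. thaliana. The AspGTC sequence that led its family was the same in all 5 species and stood 0 edits from the plastid and 1 edit from the mitochondrial A. thaliana sequence. In the grasses the leading GlyGCC sequence stood 13 to 15 edits from the plastid tRNA and 22 or 23 edits from any mitochondrial or nuclear one, and the leading GlnTTG sequence of H. vulgare, S. italica and T. aestivum stood 5 edits from the plastid one. The files named no compartment; it was assigned after the data were seen, by edit distance to A. thaliana, and no grass genome was used. The plastid share of a grass library therefore hung on the limit set for GlyGCC: it was 95.8% in Z. mays and 0.692% under both other limits tried, while the nuclear share of each library stayed within its counting interval under all of them.

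The comparison of YAMAT-seq with tRNA-seq in the 5 species with both assays asks how far a selection of full-length CCA-ended tRNAs changes the tRNA profile. GlyGCC was higher in YAMAT-seq in 5 of 5 species, at a mean share of 80.1% ± 15.5 (SD, n = 5) against 5.20% ± 2.62 (SD, n = 5), a mean log2 ratio of 4.06 ± 0.88. A total of 31 families were lower in 5 of 5 species, among them ThrTGT, ValAAC, LysCTT, SerTGA, GlnCTG, ThrCGT, GlyCCC, LeuTAG and LeuCAA. ThrTGT was 2.29% to 9.50% of tRNA-seq and 0.00123% to 0.0140% of YAMAT-seq, and GlnCTG was 0.117% to 21.4% against 0.000494% to 0.0113%. ValAAC was 0.544% to 11.4% of tRNA-seq and had 2 YAMAT-seq reads in S. italica and none listed in the other species. LeuTAG had 9560 reads in A. thaliana and none listed in the 4 grasses, and LeuCAA had 25079 in A. thaliana and at most 4 in a grass. Of these A. thaliana reads, 9554 and 25074 were of a plastid sequence. SerGCT was lower in the 4 grasses and higher in A. thaliana. GlnTTG was higher in 4 species and lower in Z. mays, at 0.00246% against 7.96%. Whether the reference tRNAs of the grasses held plastid LeuTAG, LeuCAA and SerGCT, and those of Z. mays plastid GlnTTG, is not given in the sources used here. Low counts of these families in a grass need not mean a loss in the assay or a difference between species.

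The pseudocount cannot change the direction of a ratio, but it set the size of these falls, because the YAMAT-seq share of these 9 families lay under 0.01% in at least 4 of 5 species. The mean log2 ratio of ThrTGT was -9.85, -8.23 and -5.40 with 0.001, 0.01 and 0.1, and that of LeuTAG was -8.70, -6.03 and -3.31, so neither the size nor the order of these falls is fixed by the data.

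GlyGCC took most of the YAMAT-seq reads, and with the pseudocount of 0.01 the median family with a mean of at least 0.1% had a log2 ratio of -3.06 in A. thaliana, -5.30 in H. vulgare, -4.84 in S. italica, -5.65 in T. aestivum and -4.88 in Z. mays. That median family was ValCAC in H. vulgare, LeuTAG in T. aestivum and ThrCGT in Z. mays, each without listed YAMAT-seq reads. In S. italica it was ProTGG at 0.00509%, below the pseudocount. The zero point in the grasses thus rests on the pseudocount and the tRNA-seq share of these families. Relative to that median, and among the 35 families with a mean of at least 0.1%, 6 were higher in 5 of 5 species and 4 were lower. Independent families with random signs would give 2.19. In the grasses these counts compare families with a nearly unread one and do not measure enrichment by the assay. GlyGCC stood 8.80 above the median on the log2 scale, AspGTC 4.86, CysGCA 4.38, TrpCCA 2.41, ThrGGT 1.20 and ArgTCT 0.88, although before this scaling AspGTC and CysGCA were lower in 3 species, TrpCCA in 4, and ThrGGT and ArgTCT in 5. ThrTGT, ValAAC, SerTGA and AsnGTT were lower in both ways of scaling. With pseudocounts of 0.001 and 0.1 as well, 5 families (GlyGCC, AspGTC, CysGCA, TrpCCA and ThrGGT) were higher and 3 (ThrTGT, ValAAC and SerTGA) lower than the median in 5 of 5 species, while ArgTCT and AsnGTT were not. With 0.001 alone, GluCTC, GlyTCC and LeuTAA were also higher and IleAAT, LeuTAG, LysCTT and ThrCGT lower in 5 of 5 species, and with 0.1 alone ValCAC was higher. With every family, 15 were higher and 4 lower after this scaling, families that are near 0 in both assays included. The size of these differences moved with the pseudocount, for AspGTC from 7.34 with 0.001 to 2.70 with 0.1.

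**Figure D2:**
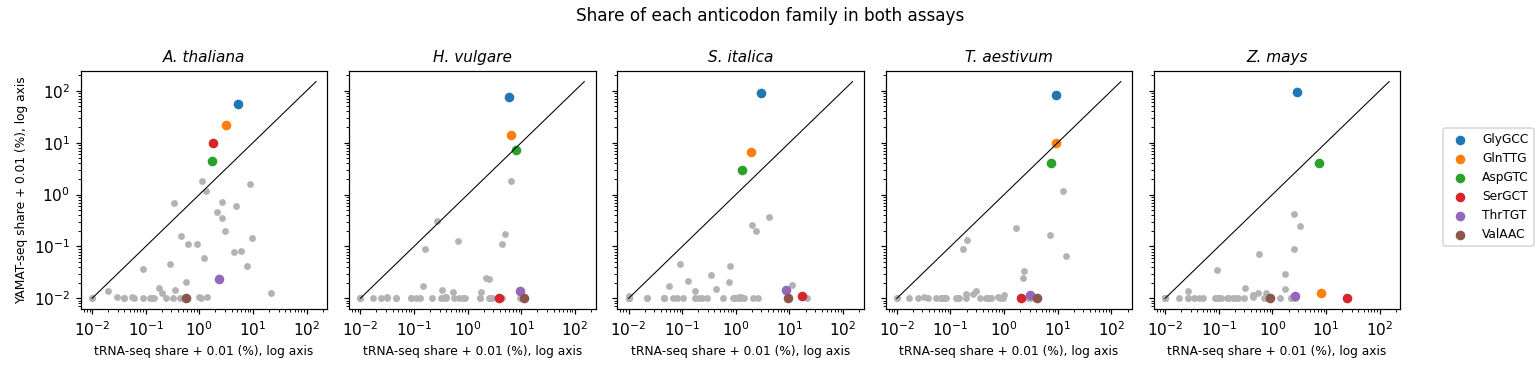
Share of each anticodon family in tRNA-seq (horizontal) and in YAMAT-seq (vertical), both in percent + 0.01 on log axes, in 1 panel per species; each point is a family, the line marks equal shares, and 6 families are coloured. GlyGCC lay above the line in 5 of 5 panels, and ThrTGT and ValAAC lay below it in 5 of 5.

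The two-sided exact sign-flip permutation test over the 5 species could not go below p = 0.063, which 32 of the 52 families reached. The smallest adjusted p of this exact test was 0.102, so no family passed. Independent families with random signs would give 3.25, but the shares of a library sum to a fixed total. The gain of GlyGCC lowers the other shares, so the excess is no separate evidence for each of the 31 lower families. Ratios carry no counting interval because the tRNA-seq depth is unknown, and the A. thaliana tRNA-seq value is that of the identical leaf and root columns. Within a species, Spearman's rho between the assays across families found in both was 0.663 in A. thaliana, 0.374 in H. vulgare, 0.174 in S. italica, 0.448 in T. aestivum and 0.566 in Z. mays. It covered 45, 33, 32, 39 and 24 families in that order. Families without YAMAT-seq reads were left out, among them SerGGA at 25.8% and SerGCT at 25.1% of tRNA-seq in Z. mays. ValAAC at 11.4% in H. vulgare and SerGGA at 21.4% in S. italica were left out too. These rho values thus omit some of the largest differences between the assays.

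Gly and Ala together were higher in YAMAT-seq in 5 of 5 species, at 56.2% to 95.1% against 3.52% to 14.8% in tRNA-seq of the same 5 species, with 1 of their 6 families (GlyGCC) higher in 5 of 5 and 2 lower. Leu and Ser, whose tRNAs have a long variable arm, were lower in 5 of 5 species, at 0% to 11.6% against 11.7% to 56.0%, with 7 of 10 families lower in every species, as were 31 of all 52; relative to the median family, 1 of the 10 (SerTGA) was lower in 5 of 5 and 0 were higher. Here and below, counts relative to the median family are of families with a mean of at least 0.1% whose direction held in 5 of 5 species with pseudocounts of 0.001, 0.01 and 0.1 alike. With 0.01 the median family of each grass had a YAMAT-seq share under 0.01%, so these counts do not measure enrichment by the assay. Glu, whose plastid tRNA starts tetrapyrrole synthesis, was lower at 0.0831% to 2.07% against 4.19% to 14.3%. MetCAT, which holds initiator and elongator tRNAs and the organelle tRNA-Ile whose gene has the same anticodon, was lower at 0.0321% to 1.82% against 1.96% to 12.5%. Asp and Glu together were lower at 3.16% to 7.39% against 11.6% to 21.8%, and Arg, Lys and His together at 0.157% to 0.967% against 5.52% to 11.5%. Relative to the median family AspGTC was higher, and no other family of Asp, Glu, Met, Arg, Lys or His held a direction with all of these pseudocounts. Phe, Tyr and Trp were higher in 1 species and lower in 4 (exact p = 0.125), with TrpCCA higher in 5 of 5 relative to the median family.

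By the first anticodon base (position 34), the sum of families with A was lower in 5 of 5 species, at 0.000671% to 0.00679% against 1.5% to 26.3%, and those of C and T were lower too, at 0.382% to 2.52% against 10% to 40.9% and at 0.425% to 25.2% against 18.6% to 41.9%. In A. thaliana all YAMAT-seq sequences with A there were nuclear except a plastid ArgACG with 773 reads. The leading A. thaliana sequences with G, C and T there were plastid. Sums by anticodon base thus cannot be told apart from the compartment. Relative to the median family, 0 of 5 families with A were higher in 5 of 5 species and 1 lower, 1 of 11 with C higher and 0 lower, and 0 of 10 with T higher and 2 lower. The sum of the 13 families with G at that position was higher, at 72.3% to 99.2% against 17.6% to 68.7%, but of these families only GlyGCC was higher in 5 of 5 species and 4 were lower; relative to the median family 4 of 9 were higher and 0 lower. Likewise the sum of the 28 families with 2 or 3 G or C in the anticodon was 75.4% to 99.3% against 37.7% to 70.5%, with GlyGCC alone higher in 5 of 5 and 15 lower, but 5 of 18 higher and 0 lower relative to the median family. The sum of the 24 families with 0 or 1 G or C, its complement, was 0.684% to 24.6% against 29.3% to 62.3%, with 0 higher in 5 of 5 and 16 lower, and 0 of 17 higher and 3 lower relative to the median family. Each of these sums except the aromatic one reached the smallest exact p of 0.063, and none could pass a threshold of 0.05, adjusted over the list alone or over all families. No entry was labelled as other than a standard tRNA (0 entries). The grass YAMAT-seq entries are named by a running number alone, so a pseudogene or undetermined tRNA could not be recognised among them.

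In A. thaliana the tRNA-seq share of a family was compared with the number of its nuclear genes in TAIR10.1 and with the use of its amino acid in the annotated proteins, and so was the share of nuclear-type YAMAT-seq reads. Over 47 families Spearman's rho with gene number was 0.278 (permutation p = 0.0578, adjusted p = 0.116) in tRNA-seq and 0.299 (permutation p = 0.0415, adjusted p = 0.116) in YAMAT-seq, with Pearson's r of 0.210 (permutation p = 0.159) and 0.111 (permutation p = 0.412). Among these families, IleCAT and GlyACC had 1 gene each and entered with 0 in both assays. Neither is listed as an anticodon of tRNA-seq, so their 0 there is not a measured value. The tRNA-seq values name no compartment and may hold organelle tRNAs, while the gene number is nuclear alone. The nuclear-type YAMAT-seq reads were led by AspGTC, GluCTC and GluTTC with 62138, 62060 and 52092. Over the 10 families with at least 100 of these reads, rho with gene number was 0.248. Over 20 amino acids rho with amino acid use was 0.364 (permutation p = 0.114, adjusted p = 0.151) and 0.302 (permutation p = 0.196, adjusted p = 0.196), with r of 0.271 (permutation p = 0.251) and 0.215 (permutation p = 0.363). None of these 4 relations passed after Benjamini-Hochberg adjustment, the last had a rho of -0.133 over the 9 amino acids with at least 100 counts, and families are not independent replicates.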

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

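The results here were picked by a rule of opposite directions in A. thaliana and in all 4 grasses, and the differences themselves were not tested. The test of the Leu and Ser families in A. thaliana was set down before its result was seen, and its repeats with other pseudocounts were chosen after.

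In the ratio of YAMAT-seq to tRNA-seq, SerGCT had a log2 value of 2.48 in A. thaliana and between -11.3 and -7.70 in the grasses, where the size is set by the pseudocount of 0.01. TrpCCA had 0.69 in A. thaliana and between -4.21 and -2.38 in the grasses. AlaCGC had 0.00429 in A. thaliana, where it was listed at 0 in tRNA-seq and held 4 reads in YAMAT-seq, and between -4.43 and -0.88 in the grasses, so its A. thaliana value only reflects the pseudocount.

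SerGCT was the clearest of these, since S. italica and Z. mays had 16.9% and 25.1% of it in tRNA-seq and 77 and 0 reads in YAMAT-seq, against 9.94% of the YAMAT-seq reads in A. thaliana. A candidate explanation is that YAMAT-seq captures tRNAs with a long variable arm poorly in every species. In A. thaliana the Leu and Ser families had a median of -1.41 relative to the median family and 2 of 10 above 0, which met the prediction set beforehand. With pseudocounts of 0.001 and 0.1 the median was -1.56 and -0.03 with 4 of 10 above 0. With 0.01 the median family of A. thaliana was LeuTAA, itself a member of the set. Nuclear-type reads were few in these families, with 32 of SerGCT against 1290264 of its leading plastid sequence. The tRNA-seq values name no compartment, so these ratios may compare different mixes of plastid and nuclear tRNAs. The explanation therefore stays undecided for the set. In each of the 4 grasses all 10 families lay under 0.01% of the YAMAT-seq reads, where the pseudocount sets the value, so these libraries weigh neither way. SerGCT itself has a long arm and stood at 5.54 in A. thaliana, but it was picked by its direction in this library, so its value cannot weigh against the explanation. Whether the reference tRNAs of the grasses held a plastid SerGCT, or the species differ, was not tested.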

How the results depend on the processing

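The limits of 12 edits with a gap of 3 and of 20 edits with a gap of 8, the size factor on families with a mean of at least 0.1%, the other pseudocounts alone and with it and the use of values of 0 in rank correlations were chosen after the data were seen. Of 96 alternatives over 30 results, 67 kept the result within its spread, within 1.5 times its count or on its side of the test, 28 moved it and 1 turned its direction. Of the 67, at least 16 could not have moved: 10 use leaf or root alone, which are identical, and 6 change the pseudocount alone, which cannot change a sign. Of the other 80, 51 kept the result, but some of these 51 were also settled beforehand. A minimum of 10 counts removes too few reads to change the number of leading sequences. Other edit limits cannot change an A. thaliana type set by an exact match. The A. thaliana sequences without a match lay within 1 edit of their type and far from the others. The 51 therefore overstates how many alternatives tested a result. The alternatives for leaf against root were not run, since identical columns give a ratio of 1 under each.

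With families of a mean of at least 0.1%, the median tRNA-seq rho between species was 0.363, and with amino acid sums 0 groups did not overlap between grasses and eudicots and 13 amino acids were lower in YAMAT-seq in every species; fewer units enter in each. Without the most abundant family of each library 2 families were higher in YAMAT-seq in every species. GlyGCC is the family removed from YAMAT-seq, and the other YAMAT-seq shares then rise by construction of a smaller total. The size factor gave 15 higher and 4 lower over all families, and 6 higher and 4 lower over families of at least 0.1%, since it sets the median family to 0; the latter became 9 and 7 with a pseudocount of 0.001 and 6 and 3 with 0.1. With at least 100 counts, the rho of nuclear-type YAMAT-seq reads with amino acid use turned from 0.302 to -0.133 over 9 amino acids, and the cause was not tested; neither passed. The other relations kept their sign, with rho from 0.184 to 0.486.

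Without GlyGCC, the share of nuclear-type reads was 3.01% in A. thaliana, 2.39% in H. vulgare, 7.22% in S. italica, 1.81% in T. aestivum and 5.77% in Z. mays, and that of plastid-type reads 93.0%, 68.4%, 68.9%, 72.0% and 14.2%, by construction of a smaller total. With 12 edits and a gap of 3 the plastid-type share was 16.4% in H. vulgare, 7.21% in S. italica, 11.2% in T. aestivum and 0.692% in Z. mays, and with 20 edits and a gap of 8 it was 7.21% in S. italica and 0.692% in Z. mays, because the GlyGCC sequence then has no type. Depth limits the sequences with under 10 reads, and 88 of 151 in T. aestivum are of that kind.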

Other observations

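All tests in this part, those of position 73, of the leading family and of position 9 included, were chosen only after the result was seen, as were the split of the grasses and the set of anticodons below; positions 9 and 73 were the only ones examined.

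Within the grasses, barley and wheat stood apart in tRNA-seq. LeuAAG was 9.38% in H. vulgare and 4.08% in T. aestivum and at most 0.253% in S. bicolor, S. italica and Z. mays, and SerAGA was 2.60% and 2.75% against at most 0.184%. SerGGA was listed at 0 in both and was 0.355%, 21.4% and 25.8% in the other grasses; whether the reference tRNAs of barley and wheat held it is not given in the sources used here. HisGTG was 0.355% and 0.116% against at least 1.18%. In all, 18 of 52 families did not overlap, 12 higher and 6 lower in barley and wheat, where chance gives 20%, or 10.4.

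Anticodons with organelle tRNA genes alone in TAIR10.1 (IleGAT, SerGGA, ThrGGT and ValGAC) summed to 21.5% of tRNA-seq in S. italica and 26.3% in Z. mays, nearly all of it SerGGA, and to between 0.195% and 1.91% in the other species. Each of these anticodons was listed at 0 in some species, and whether the reference tRNAs of those species held it is not given in the sources used here. In YAMAT-seq SerGGA held 1.18% in A. thaliana and no listed sequence in the 4 grasses, whose reference tRNAs are not given in the sources used here. In Z. mays GlnTTG was 7.96% of tRNA-seq, and its YAMAT-seq sequences, led by 1 with 157 reads, were all nearest to nuclear tRNAs.

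Full-length sequences that still held an intron were found for TyrGTA alone, with introns of 12 to 15 bases: 5 sequences and 18 reads in H. vulgare, 7 and 41 in S. italica, 3 and 6 in T. aestivum, 4 and 9 in Z. mays, and 0 in A. thaliana. The 4 grasses had 0 nuclear-type TyrGTA sequences without an intron. The nuclear-type TyrGTA sequence of A. thaliana, with 10 reads, was listed in spliced form, 1 edit from the mature tRNA of AT1G49460. Whether the reference tRNAs of the grasses were spliced is not given in the sources used here. The contrast with A. thaliana thus cannot be told apart from a difference between the reference lists. Of the 532 YAMAT-seq sequences, 57 (10.7%) differed at 1 base from a sequence of the same library that was at least 100 times as abundant. They held 0.00596% of the reads and 34 of them were in T. aestivum. Their origin was left open.

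Nuclear-type sequences held 0.282% to 1.35% of the YAMAT-seq reads. That 1 family alone sets this was argued against by the shares without GlyGCC, where nuclear-type reads still reached at most 7.22% in any library. Ligation that favours the base at position 73 of the leading sequence, which was C in all 5 species, could add to it: the other sequences with C had the higher median count in 4 of 5 libraries, all but Z. mays, but only in 2 of 5, A. thaliana and S. italica, did they also exceed sequences with another base in over 50% of pairs, which leaves it undecided. Of the reads without the leading sequence, those with G at position 73 held 68.5% to 91.3% and those with C 2.58% to 23.0% over the 5 libraries. The biological explanation, a high share of plastid tRNAs in seedlings, was not tested, since no tissue without plastids was analysed here. In tRNA-seq of the same 5 species GlyGCC of every type held 2.82% to 9.25%, so its excess in YAMAT-seq was not shared by both assays. The tRNA-seq values name no compartment and either assay may favour some tRNAs, so this explanation stays undecided.

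Among nuclear-type sequences, those with G at position 9 averaged lower log2 counts than those with A in 5 of 5 libraries, with a mean difference of -0.74 in A. thaliana to -2.57 in Z. mays. That a modified G9 blocks full-length cDNA is a candidate explanation, and 5 libraries had the direction it needs. The permutation p adjusted over the 5 libraries was 0.265 in A. thaliana, 0.321 in H. vulgare, 0.154 in S. italica, 0.110 in T. aestivum and 0.0535 in Z. mays, and the medians went the other way in H. vulgare (6 against 5 reads) and S. italica (12.5 against 10), so the explanation stays undecided. No biological explanation was tested.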
